A study of Mus musculus with 4 samples.

How the data were processed

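DNA methylation was measured by bisulfite sequencing in cultured mouse embryonic fibroblasts (MEFs). Bisulfite turns unmethylated cytosines into uracil, read as T, and leaves methylated cytosines as C. Per the labels, the cells were wild type (WT) or knockout (KO) for Pml, and were left untreated or treated with doxorubicin; dose and time are not given in the sources used here. Each of the 4 groups held 1 library, so no spread between replicates could be measured. Per the labels' design text, genomic DNA was digested with a restriction enzyme, short fragments were selected, and these were bisulfite converted and sequenced on an Illumina instrument. Per the submitters' processing notes, the genome build was mm9 and CASAVA 1.4 was among the tools. The aligner, the methylation caller and the filters are not given in the sources used here.

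The deposited tables list 1 CpG per line. The authors deposited counts of reads with C and of reads with T at each CpG, each split into a pair of columns that were read here as the 2 strands. The authors also deposited the fraction of methylated reads, which equalled C reads over all reads in every line within a small rounding tolerance, with 0 mismatches in each table. A further deposited column, named X per the file headers, rose within every chromosome and skipped numbers; it was taken as the running number of a CpG with any read before a coverage filter. The smallest number of reads at a listed CpG was 11 in every deposited table, so CpGs with fewer reads had been left out before deposit. By the running number, 53.5%, 49.0%, 51.6% and 47.6% of the CpGs with any read were listed in the WT untreated, WT doxorubicin, Pml KO untreated and Pml KO doxorubicin libraries. The highest running numbers of the chromosomes summed to 20896988, 20866767, 20931880 and 20854764 CpGs with any read in these libraries. That breadth is close to a whole-genome library, while the design text describes a digest with size selection. Both are given here as found.

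No gene annotation of build mm9 was used here. The gene table at hand belongs to another build, and coordinates of different builds were not mixed. Promoters, gene bodies and the 19 gene lists fixed before the data were examined were therefore not analysed here. The fixed fallback was used instead: the promoter test was run on 1 kb windows of the genome, and for each comparison the 5 called windows with the largest rise and the 5 with the largest fall were named by position. CHG and CHH sites, planned as a measure of incomplete conversion, were not used here because the tables list CpGs. The level of mitochondrial CpGs was taken as an upper bound on unconverted reads instead.

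Counts of the 2 strands of a CpG were summed. A CpG entered a comparison with at least 10 reads in both libraries. For each CpG, C and T reads of the libraries were compared with a two-sided Fisher's exact test, p-values were adjusted by the Benjamini-Hochberg method over all CpGs of the comparison, and a CpG was called at an adjusted p under 0.05 with a difference of at least 25 percentage points. Windows of 1 kb with at least 5 such CpGs were tested in the same way on summed reads and called with a difference of at least 10 points in the mean CpG level. A read that covers several CpGs counts at each, so window p-values are too small, which is why a size threshold was set. A different doxorubicin change between genotypes was tested per CpG by a z statistic of the difference of the log odds ratios, with 0.5 added to every count, over CpGs with enough reads in all 4 libraries. With 1 library per group, each of these tests compares libraries, not conditions. Wilson intervals at the 95% level cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

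Region classes were chromosomes, classes of CpG density (listed CpGs per 1 kb) and classes of methylation level of 100 kb windows, the last assigned from a library outside the comparison. Windows of 100 kb needed at least 50 autosomal CpGs with at most 100 reads in each library. The relative read depth of an autosome was the mean of a negative binomial distribution fitted to the number of CpGs below the coverage filter and to the read numbers of listed CpGs, divided by the median autosome of that library. Segments were compared by the share of CpGs listed in Pml KO untreated over that in WT untreated, among the CpGs listed in any library, in windows of 1 Mb. The strands of each CpG within a library were also compared by the same Fisher's exact test. That comparison takes in strand differences that libraries share, so it does not measure the noise between libraries. In 10 draws, the reads of the untreated and doxorubicin libraries were also redistributed at random at each CpG.

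The alternatives were coverage minimum, size threshold, thinning to equal reads, strands as separate sites, deepest CpGs left out, autosomes only, read numbers divided by a strand inflation factor, 1 CpG per window, another weighting and another interaction statistic. Window size, a limit of 100 reads and a restriction to the 7 autosomes of lowest depth in Pml KO were added after the data were seen. The tests were checked on simulated reads at the real read numbers. These reads were drawn independently at each CpG, without the strand inflation and shared reads of the data, so the results may be too favourable. The number of changed CpGs differed between comparisons and enters the adjustment, so recovered shares cannot be compared between them. For WT doxorubicin minus WT untreated, over 8348564 CpGs with 200 changed CpGs per size, 5.5% of changes of 30 points, 17.5% of changes of 50 points and 55.5% of changes of 80 points were recovered, with 2 calls among unchanged CpGs. For Pml KO untreated minus WT untreated, over 8373254 CpGs with 60000 changed per size, the shares were 13.1%, 44.4% and 95.9%, with 751 calls among unchanged CpGs. The window test of WT doxorubicin minus WT untreated, over 639349 windows, recovered 36.0%, 73.0% and 99.0% of changes of 15, 25 and 40 points. The interaction test, over 5882714 CpGs with 200 changed per size in Pml KO alone, recovered 0.5% of differences of 50 points and 4.5% of differences of 80 points. Its sensitivity at these depths and that number of changed CpGs was low. The fitted depth deviated by at most 0.11% from the simulated one. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9 were used.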

Results

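DNA methylation at CpGs was measured in MEFs, connective tissue cells grown from mouse embryos, that carried intact Pml or lacked it. Pml encodes the promyelocytic leukaemia protein, the scaffold of PML nuclear bodies. Doxorubicin, an anthracycline that poisons topoisomerase II and breaks DNA, was given to a culture of each genotype. Each group held 1 library, so no comparison of 2 groups below has replicates of its own, and a test on reads compares 2 libraries, not the conditions. The doxorubicin and genotype differences were each measured in 2 separate pairs of libraries, but the genotype pairs may rest on the same lines. The tables list 11173510 CpGs in WT untreated, 10218586 in WT doxorubicin, 10810148 in Pml KO untreated and 9925963 in Pml KO doxorubicin. Reads at listed CpGs totalled 382325250, 357580095, 342807733 and 331033739, with a median of 16 reads per listed CpG in each library. Of 15080138 CpGs listed in any library, 5882714 were listed in all 4. All positions are on build mm9, 1-based, as the tables give them.

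The targeted gene, Pml, was not located on this build, so the genotype labels were not checked on it. A scan for stretches without listed CpGs found none of 20 kb in both Pml KO libraries among 112652 windows with at least 20 listed CpGs in both WT libraries. At 2 kb, with at least 10 listed CpGs in both WT libraries, the scan found 41 such windows among 347200, of which 0 lay on chromosome 9, which carries Pml. The scan could not find a change that leaves CpGs listed in each window, so the 0 does not test the knockout. Of the 41 windows, 18 lay on chromosome 1 from 85122001 to 85308000. That stretch listed 1709 CpGs at a median of 71 reads in WT untreated and 637 at a median of 30 reads in Pml KO untreated, so part of it was covered in both genotypes. In the opposite direction the scan at 2 kb found 20 windows among 331935. A stretch of chromosome 4 from 88877874 to 89037311, 159438 bp long, held 0 listed CpGs in WT untreated and 2 in WT doxorubicin. The Pml KO untreated and doxorubicin libraries listed 392 and 391 CpGs there.

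**Figure D1:**
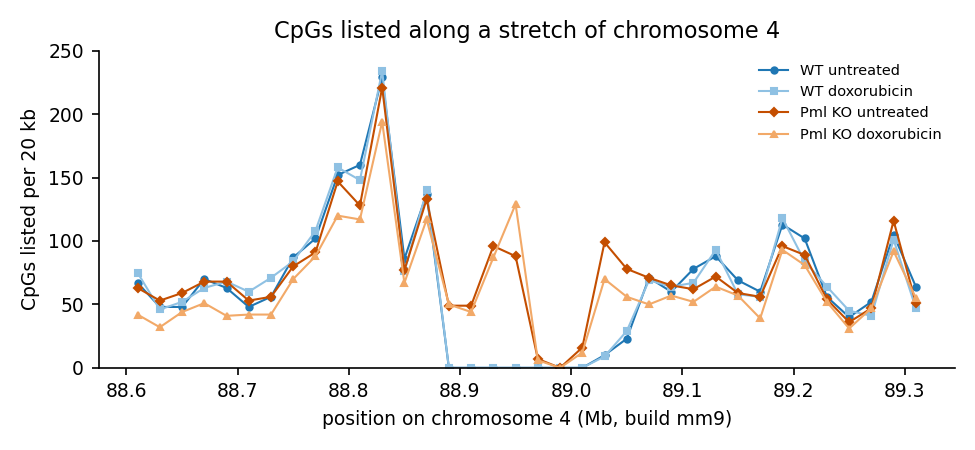
CpGs listed per 20 kb (vertical axis) along chromosome 4 (horizontal axis, Mb, build mm9), with 1 line per library. Both WT lines lie at 0 from 88880001 to 89020000, where the Pml KO libraries list 49 and 50 CpGs in the first 20 kb.

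The genotypes also differed in the relative depth of whole chromosomes. In Pml KO untreated, chromosomes 8, 14, 15 and 19 had a relative depth of 1.34, 1.30, 1.30 and 1.36, against values between 0.953 and 1.005 in WT untreated. Chromosome 6 stood at 1.29 in WT untreated and at 1.21 in Pml KO untreated. Relative to the 7 autosomes of lowest depth in Pml KO, it stood at 1.335 and 1.377, so which was larger depended on the reference. The pair of libraries of a genotype matched: the largest difference over the 19 autosomes was 0.029 between the WT libraries and 0.016 between the Pml KO libraries, against 0.355 between the untreated libraries of the genotypes. Depth also changed within chromosomes. The share of CpGs listed in Pml KO untreated over that in WT untreated, as medians of 10 windows of 1 Mb, went from 0.835 to 0.504 on chromosome 4 at 129000001 and from 0.769 to 1.09 on chromosome 3 at 96000001. The X chromosome had 26.9% of its CpGs with any read listed in WT untreated and 27.8% in Pml KO untreated, where all CpGs gave 53.5% and 51.6%.

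**Figure D2:**
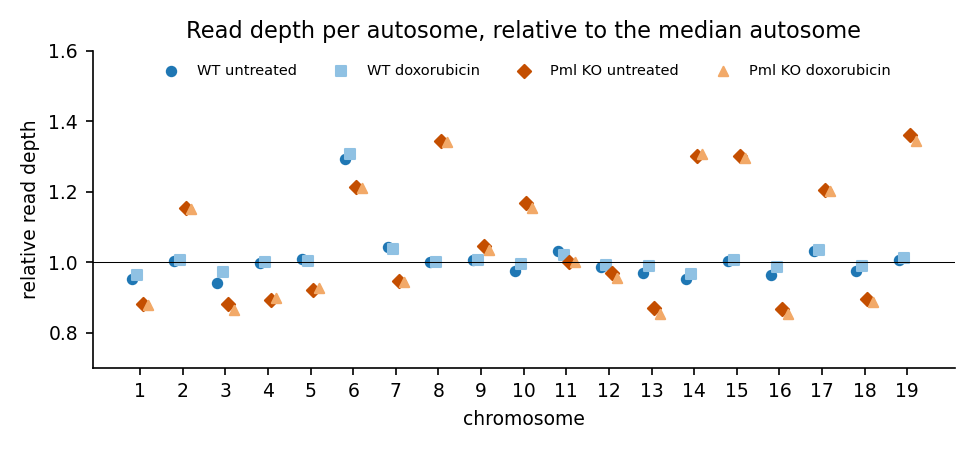
Relative read depth (vertical axis, 1 is the median autosome of the library) for each of the 19 autosomes (horizontal axis), with 1 point per library. Chromosomes 8, 14, 15 and 19 lie at 1.30 or above in Pml KO untreated and within 0.953 to 1.005 in WT untreated.

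The methylation level over the CpGs listed in all 4 libraries was lowest in WT. Weighted by reads, it was 60.4% in WT untreated, 60.8% in WT doxorubicin, 64.5% in Pml KO untreated and 65.2% in Pml KO doxorubicin. The 95% Wilson intervals ran from 60.4% to 60.5%, from 60.8% to 60.8%, from 64.5% to 64.5% and from 65.2% to 65.2%. With each CpG weighted equally the levels were 58.4%, 58.9%, 63.3% and 63.7%. CpGs below 10% methylation made up 16.2% of the total in WT untreated, 15.95% in WT doxorubicin, 12.3% in Pml KO untreated and 12.2% in Pml KO doxorubicin. Mitochondrial CpGs, which bound the share of unconverted reads, stood at 0.484%, 0.453%, 0.570% and 0.593%.

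The first comparison asked whether doxorubicin changed methylation in WT cells. Few CpGs were called between WT doxorubicin and WT untreated, by a test that recovered 17.5% of simulated changes of 50 points. Of 8348564 CpGs tested, 99 were called, 46 higher and 53 lower in the doxorubicin library, by Fisher's exact test with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was reached by 2.29% of CpGs. Redistributed reads gave at most 0 calls in 10 draws. The draws assume, as the test does, that reads differ by counting error alone, so few calls were bound to result. Within WT untreated, the strands of a CpG differed by the same thresholds at 1.005% of CpGs with at least 10 reads on each strand. The share called here was 0.0012%, so the strand share is no noise level for a comparison of libraries. The called CpGs were deep, with a median of 81 reads in the doxorubicin and 72 in the untreated library, against 17 and 18 over all CpGs tested. They were also isolated: the nearest CpG within 200 bp of a CpG called higher differed by 4.59 points on average, against 43.5 points at the called CpGs themselves, and 51.4% of these neighbours were higher in the doxorubicin library.

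Among 1 kb windows, 332 were higher and 222 lower in WT doxorubicin, of 639349 tested. Levels of called windows, here and below, cover only the CpGs with enough reads in both libraries compared. Over all CpGs listed in each library, a window can differ by more or by less. The largest rise lay on chromosome 11 from 41103001 to 41104000, from 7.1% to 46.0% over 5 CpGs (adjusted p 3.84e-06, Fisher's exact test on 96 and 95 reads). On chromosome 12 from 29681001 to 29682000 the level was 53.2% untreated and 91.1% with doxorubicin, and on chromosome 2 from 33361001 to 33362000 it was 35.7% and 72.6%. Windows on chromosome 11 from 100256001 to 100257000 and on chromosome 17 from 26482001 to 26483000 were higher by 34.8 and 34.3 points. The most significant of the 5 largest falls was on chromosome 5 from 49168001 to 49169000, from 47.9% to 12.9% over 10 CpGs (adjusted p 1.16e-18, Fisher's exact test on 234 and 531 reads). Windows on chromosome 5 from 147755001 to 147756000, chromosome 10 from 82511001 to 82512000, chromosome X from 103684001 to 103685000 and chromosome 13 from 39208001 to 39209000 were at 86.0%, 82.8%, 77.2% and 66.1% untreated and at 51.1%, 49.2%, 45.4% and 34.7% with doxorubicin. With the deepest CpG of each window alone, 16 windows were called and falls outnumbered rises, 10 to 6.

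By region, the mean level of WT doxorubicin lay above that of WT untreated on every chromosome, by 0.37 points on chromosome 2 at the least among the autosomes and by 0.52 points on chromosome 1 at the most. The autosomal difference was 0.44 points and that of the X chromosome 0.58 points, but weighted by reads they were 0.38 and 0.31 points, so which was larger depended on the weighting. Windows with 1 to 4 listed CpGs per kb differed by 0.51 points and CpG-dense windows with 40 or more by 0.17 points. Weighted by reads, the difference in CpG-dense windows was -0.28 points, the opposite sign. Of 2416 windows of 1 Mb, 91.9% were higher in WT doxorubicin. Their mean difference was 0.493 ± 0.406 points (SD of windows). Single-CpG differences had an SD of 11.5 points, which includes counting error and is no measure for a mean over many CpGs. No replicate gives the spread between cultures.

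In Pml KO cells the same question gave a similar count of CpGs, but fewer 1 kb windows, 245 (0.041%) against 554 (0.087%) in WT. Of 7885101 CpGs, 71 were called, 40 higher and 31 lower in Pml KO doxorubicin than in Pml KO untreated, by Fisher's exact test with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was reached by 2.25% of CpGs. Redistributed reads gave at most 0 calls in 10 draws, which again assume counting error alone. Within Pml KO untreated, the strands of a CpG differed by the same thresholds at 1.123% of the CpGs compared, against 0.0009% called here. The called CpGs had median depths of 66 and 59 reads, against 17 over all CpGs tested in each library. CpGs next to those called higher differed by 3.96 points on average, against 48.4 points at the called CpGs, with 41.9% of the neighbours higher.

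Of 604823 windows of 1 kb, 139 were higher and 106 lower in Pml KO doxorubicin. With the deepest CpG of each window alone, 12 were called, 5 higher and 7 lower. The largest rise was on chromosome 9 from 114018001 to 114019000, from 44% to 88.4% over 5 CpGs (adjusted p 0.000248, Fisher's exact test on 67 and 61 reads). Windows on chromosome 14 from 50733001 to 50734000, chromosome 5 from 131192001 to 131193000, chromosome 4 from 130933001 to 130934000 and chromosome 3 from 107394001 to 107395000 were higher by 37.7, 36.5, 32.3 and 32.2 points. The largest fall was on chromosome 1 from 159626001 to 159627000, from 53.8% to 16.6% over 6 CpGs (adjusted p 0.00314, Fisher's exact test on 74 and 100 reads). On chromosome 4 from 126929001 to 126930000 the level was 54.1% untreated and 23.0% with doxorubicin over 13 CpGs. Windows on chromosome 6 from 84028001 to 84029000, chromosome 1 from 98645001 to 98646000 and chromosome 3 from 65470001 to 65471000 were at 65.1%, 80% and 69.4% untreated and at 32.2%, 48.1% and 38.3% with doxorubicin. Over all CpGs listed in each library, that window on chromosome 3 was at 44.2% untreated and 35.9% with doxorubicin. The window on chromosome 4 from 130933001 was then at 30.4% and 41.1%. The window on chromosome 3 from 107394001 differed by more, at 15.5% and 62.4%. The autosomal mean was 0.41 points higher with doxorubicin, the X chromosome 0.49 points and the CpG-dense windows 0.17 points, and 90.7% of 1 Mb windows were higher. Weighted by reads, these differences were 0.69, 1.62 and 0.89 points.

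The doxorubicin comparisons of the genotypes shared few called sites. Of the CpGs tested in both, 44 were called higher in WT and 39 in Pml KO, and 0 were called higher in both. Among those called lower, 49 in WT and 25 in Pml KO, 2 were shared, against 0.0 for independent lists. Calls in opposite directions also occurred: 2 of those higher and 3 of those lower in WT were called the other way in Pml KO. Of 285 windows higher in WT doxorubicin, 52.6% had a positive difference in Pml KO, with a median of 0.19 points, and 0 were called higher there, against 0.07 for independent lists. Of 180 windows lower in WT doxorubicin, 55.0% had a negative difference in Pml KO, with a median of -0.93 points, and 2 were called lower there, against 0.04 for independent lists. Over 22485 windows of 100 kb the doxorubicin differences of the genotypes had a Pearson r of 0.028, and over 2416 windows of 1 Mb an r of 0.141; windows are not independent replicates.

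A difference between the doxorubicin changes of the genotypes was called at 37 of 5882714 CpGs, with 24 rising more in Pml KO and 13 rising more in WT. The count depended on the statistic: the difference of levels over its binomial standard error called 338, with 180 rising more in Pml KO and 158 in WT. The lowest adjusted p among the 37, 7.31e-11 by the z statistic on reads, was at position 84879507 on chromosome 10, where the level was 46.7% untreated and 66.0% with doxorubicin in WT and 54.8% and 47.3% in Pml KO. At position 65856897 on chromosome 11, the level went from 70.9% to 1.5% with doxorubicin in WT and from 10% to 87.5% in Pml KO, over 20 to 66 reads. At position 88805344 on chromosome 15 it was 17.3% and 77% in WT and 40.2% and 36.0% in Pml KO. These CpGs were singled out after their values were seen. All 37 had changes of opposite sign in the genotypes, and 31 had over 100 reads in at least 1 library. Opposite changes and high depth make a call more likely, so both may follow from the test. Most changes in 1 genotype alone were not detectable at this depth if few CpGs changed. Simulated differences of 80 points, set in Pml KO alone at 200 CpGs, were called at 4.5% of them.

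Genotype, by contrast, separated the untreated libraries over much of the genome. Methylation was higher in Pml KO untreated than in WT untreated at 254698 CpGs and lower at 90091, of 8373254 tested (Fisher's exact test with Benjamini-Hochberg adjustment), so that 4.12% were called and 73.9% of the calls were rises. The strands within WT untreated and within Pml KO untreated differed by the same thresholds at 1.005% and 1.123% of CpGs. Those CpGs had at least 10 reads on each strand, and these shares are no noise level for the genotype calls. Among 648977 windows of 1 kb, 127550 were higher and 25707 lower. Neighbouring CpGs moved together: the nearest CpG within 200 bp differed by 23.4 points on average beside CpGs called higher, and by -20.03 points beside CpGs called lower.

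**Figure D3:**
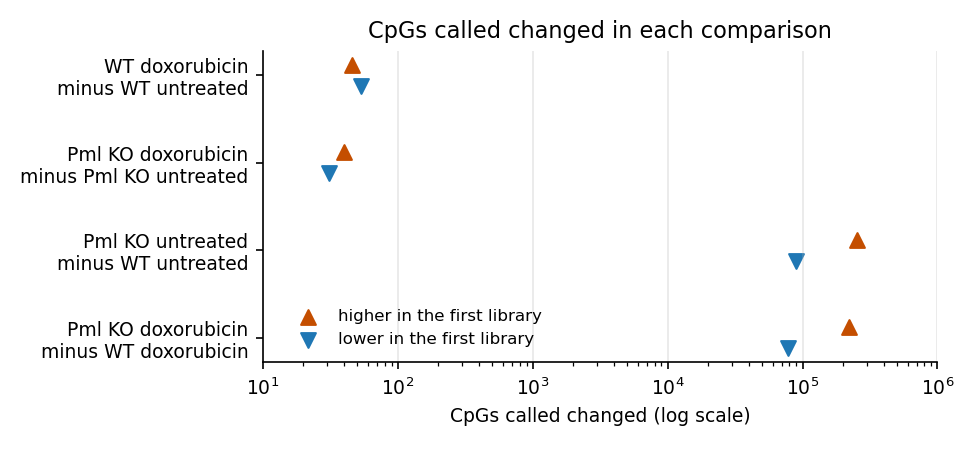
CpGs called changed (horizontal axis, log scale) in each comparison (vertical axis), with upward triangles for CpGs higher and downward triangles for CpGs lower in the first library named. The doxorubicin comparisons hold 31 to 53 CpGs per direction and the genotype comparisons 78470 to 254698.

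The windows with the largest rises in Pml KO untreated went from nearly unmethylated to nearly fully methylated. On chromosome 11 from 96195001 to 96196000 the level was 0.0% in WT untreated and 90.7% in Pml KO untreated over 5 CpGs (adjusted p 1.26e-32, Fisher's exact test on 79 and 72 reads). Over the CpGs listed in each, the WT and Pml KO doxorubicin libraries were at 1.2% and 91.3%. On chromosome 5, windows from 131735001 to 131736000 and from 131369001 to 131370000 were at 6.0% and 12.5% in WT and at 91.8% and 93.5% in Pml KO. Windows on chromosome 17 from 50182001 to 50183000 and on chromosome 9 from 32264001 to 32265000 were higher by 84.2 and 81.5 points. The largest fall was on chromosome 2 from 115887001 to 115888000, at 92.9% in WT untreated and 0.0% in Pml KO untreated over 8 CpGs (adjusted p 8.43e-50, Fisher's exact test). A window on chromosome 6 from 91162001 to 91163000 held 30 CpGs at 87.9% in WT untreated and 1.2% in Pml KO untreated (adjusted p 1.1e-235, Fisher's exact test on 512 and 638 reads). Windows on chromosome 13 from 31077001 to 31078000, chromosome 3 from 141520001 to 141521000 and chromosome 7 from 133768001 to 133769000 were at 98.1%, 91.4% and 91.0% in WT and at 7.6%, 4.6% and 5.5% in Pml KO.

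The rise was larger in domains of low methylation than in domains of high methylation. In 100 kb windows at 20 to 40% in WT doxorubicin, a library outside the comparison, Pml KO untreated was higher than WT untreated by 10.5 ± 5.29 points (SD of 4695 windows), and in windows at 80 to 100% by 0.43 ± 2.48 points (SD of 1800 windows). WT doxorubicin shares its genotype with 1 library of the comparison, so this classing picks windows that are low in WT. When the windows were classed by the mean of both doxorubicin libraries, the values were 9.57 and 1.02 points. The 49 windows below 20% then differed by 7.57 points, less than the class above them. Windows below 40% made up 23.3% of all in WT untreated and 10.4% in Pml KO untreated. By CpG density, the difference was 6.69 points in windows with 1 to 4 listed CpGs per kb, 4.66 points with 10 to 19 and -0.33 points with 40 or more. In that densest class the difference was -1.58 points weighted by reads and 1.58 points with a minimum of 20 reads, so its sign depended on the setting. The X chromosome differed by 7.55 points and the autosomes by 4.76 points, but weighted by reads by 3.23 and 4.11 points, so which was larger depended on the weighting. On the 7 autosomes of lowest depth in Pml KO, which are chromosomes 1, 3, 4, 5, 13, 16 and 18, the difference was 4.78 points.

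**Figure D4:**
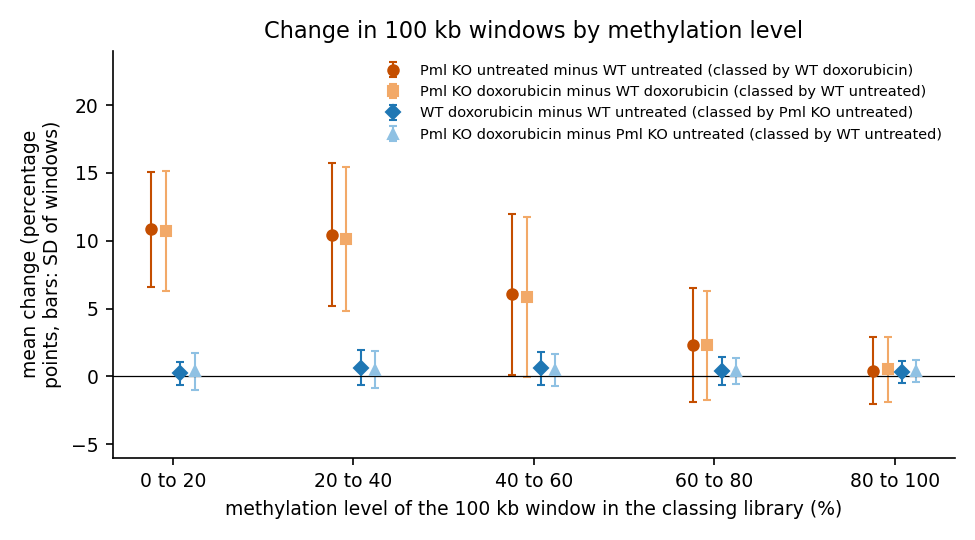
Mean change of 100 kb windows in percentage points (vertical axis, bars are the SD of windows) by methylation level of the window in a library outside the comparison (horizontal axis, %), with 1 symbol per comparison. Classed by a WT library, which picks windows low in WT, the genotype differences decline from 10.8 and 10.7 points in the lowest class to 0.43 and 0.52 points in the highest, while the doxorubicin differences lie between 0.23 and 0.65 points. Classing by the mean of both genotypes is not drawn.

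With doxorubicin, the genotypes differed in nearly the same way. Pml KO doxorubicin was higher than WT doxorubicin at 220197 CpGs and lower at 78470, of 7515727 tested (Fisher's exact test with Benjamini-Hochberg adjustment), and 107289 windows of 1 kb were higher and 22492 lower, of 568562. These libraries are not those of the untreated comparison. Relative depth over the autosomes, however, correlated at 0.99 between the WT libraries and at 0.999 between the Pml KO libraries. The pairs may therefore rest on the same WT and Pml KO lines, and their agreement does not replicate an effect of Pml. Of 97490 windows called higher in the untreated pair and tested in both, 58.3% were called higher with doxorubicin and 96.9% had a positive difference; independent lists would share 18558.82 windows, and 56825 were shared. Of 19004 windows called lower, 53.4% were called lower again. Across 100 kb windows the genotype differences of the pairs had a Pearson r of 0.966. The autosomal difference was 4.73 points, the X chromosome 7.46 points and windows with 1 to 4 listed CpGs per kb 6.72 points. Weighted by reads, the autosomes differed by 4.42 points and the X chromosome by 4.53 points.

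Some of the windows named in this comparison, on chromosomes 2, 5, 6 and 11, matched or lay near windows named for the untreated pair. The largest rise was on chromosome 13 from 32302001 to 32303000, at 0.0% in WT doxorubicin and 94.2% in Pml KO doxorubicin over 5 CpGs (adjusted p 3.77e-29, Fisher's exact test on 57 and 69 reads). On chromosome 11, windows from 96187001 to 96188000 and from 96205001 to 96206000 were at 1.5% and 0.0% in WT doxorubicin and at 94.2% and 85.7% in Pml KO doxorubicin, within 10 kb of the window named above. On chromosome 5, windows from 131399001 to 131400000 and from 131460001 to 131461000 were higher by 91.7 and 84.0 points. The window on chromosome 6 from 91162001 to 91163000 was at 85.9% and 0.4% over 24 CpGs (adjusted p 5.7e-160, Fisher's exact test on 350 and 464 reads). On chromosome 2 from 115886001 to 115887000, adjacent to the window named in the untreated pair, the levels were 97.1% and 9.5%. Windows on chromosome 10 from 66477001 to 66478000, chromosome 6 from 51123001 to 51124000 and chromosome 1 from 140412001 to 140413000 differed by -94.0, -86.2 and -85.1 points. Over all CpGs listed in each library, the window on chromosome 10 was at 88.4% in WT doxorubicin and 18.8% in Pml KO doxorubicin.

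Switches between low and high methylation were few in CpG-dense windows. Of 12004 windows with 40 or more listed CpGs per kb, 5395 were below 10% in all 4 libraries. None was above 50% in both Pml KO libraries and below 10% in both WT libraries, and 3 were the reverse. These were on chromosome 8 from 123011001 to 123012000, chromosome 9 from 81525001 to 81526000 and chromosome 17 from 18047001 to 18048000, at 62.5%, 72.1% and 65.8% in WT untreated and at 8.7%, 6.8% and 7.0% in Pml KO untreated. The levels rest on the 6, 32 and 31 CpGs listed in all 4 libraries, and the window on chromosome 8 was at 51.7% in WT doxorubicin. No CpG-dense window crossed from below 10% to above 50%, or back, between the untreated and doxorubicin libraries of a genotype.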

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

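The tests of conversion, of copies of chromosomes and segments, of relative depth between genotypes, of the regional correlation and of the chromosome 4 stretch were chosen after the results were seen; those on neighbouring CpGs and on equal read numbers were not.

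A difference between genotypes in the doxorubicin change was called at 37 CpGs, as given in the report, by the z statistic on reads, and at 338 by the other statistic.

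Relative depth drew attention because the methylation comparisons do not use it. Chromosome 6 stood at 1.29 in WT untreated and 1.31 in WT doxorubicin. In Pml KO untreated and Pml KO doxorubicin, chromosome 8 stood at 1.34 and 1.34, chromosome 14 at 1.30 and 1.31, chromosome 15 at 1.30 and 1.30, and chromosome 19 at 1.36 and 1.34.

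The stretch of chromosome 4 without listed CpGs in WT was the third signal outside the comparisons. At a depth of 11.97 reads per CpG on chromosome 4, a coverage filter alone would leave nearly every CpG with some read, but of the CpGs with any read in the best covered library, Pml KO doxorubicin, the number with any read was 30.5% in WT untreated and 26.9% in WT doxorubicin. Reads can be placed there, since Pml KO untreated listed 392 CpGs. The share without reads gave a mean of 0.36 reads per CpG in WT untreated and 0.31 in WT doxorubicin, and a minority of cells that keep the stretch cannot be told apart from reads placed there wrongly, because the reads themselves were not used here. A deletion carried by most WT cells is a candidate explanation and was not tested further.

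The higher methylation of Pml KO was the largest difference between groups. Unconverted reads account for little of it: the mitochondrial level differed by 0.086 points between the untreated libraries and by 0.14 points between the doxorubicin libraries, against 4.76 points on the autosomes. Single-CpG strain variants would leave neighbours in place, but the nearest CpG beside those called higher was higher by 23.4 points on average. The SD of neighbours was 26.8 points, 78.5% of them were higher, and 63.6% were higher by at least 10 points. Such variants cannot account for all calls, but they were not excluded for a part of them. Extra copies that act only on their own CpGs would spare the chromosomes of lowest depth, which differed by 4.78 points. They would also spare the 604 windows of 1 Mb least covered in Pml KO relative to WT, which differed by 4.55 points. An effect of extra copies on the rest of the genome was not tested. Nor was a difference in library preparation or sequencing run between the genotypes. The line itself also stays open. The relative depth of the autosomes correlated at 0.278 between the untreated libraries of the genotypes, so the genotypes differ in chromosome content. They differ at the stretch of chromosome 4 as well. The loss of Pml cannot be told apart from a separate culture history. Either could give the rise in low-methylated domains, and replicate lines would be needed to separate them.

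The small rise of the doxorubicin libraries appeared in both genotypes. The mitochondrial level, an upper bound on unconverted reads, moved the other way in WT, by -0.031 points. In Pml KO it moved by 0.023 points, against 0.44 points on the autosomes of WT. A bound does not give the change in unconverted reads itself. Lower depth was tested on CpGs with equal read numbers, where the mean change was still 0.4 points in WT and 0.416 points in Pml KO. A shift of library preparation or sequencing run cannot be told apart from the drug, since each treatment has its own library. The correlation of the changes of the genotypes, 0.028 across 100 kb windows and 0.141 across 1 Mb windows, does not decide between them. An effect of doxorubicin on methylation maintenance may be present but stays untested.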

How the results depend on the processing

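The choices of the alternatives were made before the data were examined, except those with at most 100 reads, on the 7 chromosomes of lowest depth and with other window sizes, which were chosen after seeing the data. At least 5 reads gives nothing else, since no listed CpG has fewer than 11; alternatives on promoters and gene lists were not run, for lack of an annotation. The groups share fewer than 2 replicate numbers, so samples were not paired by number. Paired within genotype, the autosomal doxorubicin differences were 0.44 and 0.41 points, and paired within treatment, the genotype differences were 4.76 and 4.73 points. An exact sign-flip test, two-sided and chosen after seeing the data, gave p 0.5 for each, the smallest p that 2 pairs allow. The genotype pairs may rest on the same lines, so they are not independent replicates. In both genotype comparisons rises outnumbered falls under each of 11 alternatives for CpGs (72.7% to 78.7% higher) and 6 for windows (79.0% to 91.4%). In the doxorubicin comparisons the majority turned under 2 of 11 alternatives for WT CpGs (43.4% to 57.1% higher), 1 of 11 for Pml KO CpGs (48.7% to 62.5%) and 1 of 6 for the windows of each (37.5% to 67.2% and 41.7% to 69.9%). Among alternatives chosen beforehand, 19 counts stayed within 1.5 times the reported count, 27 were lower and 6 higher, and 20 levels lay outside their 95% interval. Among those chosen after seeing the data, 8 counts stayed within that factor, 12 were lower, and 4 levels lay outside. These tallies leave out the differences by region class. For those, among alternatives chosen beforehand, 6 were rated the same, 31 as moved and 3 as of opposite sign. Except where fewer CpGs, windows or reads were tested, the cause was not tested.

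Levels are given in the order WT untreated, WT doxorubicin, Pml KO untreated and Pml KO doxorubicin. They were 60.9%, 61.2%, 64.8% and 65.7% with at least 20 reads; 58.4%, 58.9%, 63.3% and 63.7% with each CpG weighted equally. Over every CpG listed in the library they were 59.9%, 60.4%, 64.1% and 64.6%, and on autosomes 61.0%, 61.3%, 65.1% and 65.8%. With the CpGs with the most reads left out they were 60.5%, 60.9%, 64.6% and 65.4%, and with at most 100 reads and equal weights 58.2%, 58.6%, 62.9% and 63.3%.

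CpGs called between the doxorubicin and untreated libraries of WT and of Pml KO numbered 167 and 119 at a difference of at least 10 points, and 52 and 46 at 40 points. They numbered 46 and 39 with reads divided by the strand inflation factor, 28 and 24 with 1 CpG per window, 30 and 31 with at most 100 reads, and 27 and 16 on the chromosomes of lowest depth. In WT 65 were called with reads thinned to equal numbers, and in Pml KO 139 with each strand as a site.

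CpGs called between the genotypes, untreated and with doxorubicin, numbered 112229 and 96365 with at least 20 reads, 202435 and 179509 with reads thinned, and 129481 and 92490 with reads divided by the inflation factor. They numbered 96427 and 88152 with 1 CpG per window, 134360 and 128470 with each strand as a site, and 98585 and 85469 on the chromosomes of lowest depth. A different doxorubicin change was called at 59 CpGs with at least 20 reads, 66 at a difference of at least 10 points and 338 with the difference of levels over its binomial standard error.

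Windows called by doxorubicin in WT and Pml KO numbered 150 and 69 at 20 points, 16 and 12 with the deepest CpG alone, 332 and 122 with at most 100 reads, and 200 and 76 on the chromosomes of lowest depth. Windows called between genotypes, untreated and with doxorubicin, numbered 62616 and 52687 at 20 points, and 60387 and 52583 with the deepest CpG alone. They numbered 31257 and 26743 with at least 20 reads, and 43147 and 36341 on the chromosomes of lowest depth.

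The sign turned for the change in windows with 40 or more CpGs per kb. It was -0.28 points for doxorubicin in WT weighted by reads, and 1.58 and 1.65 points for Pml KO minus WT, untreated and with doxorubicin, with at least 20 reads. Depth and the number of changed CpGs both limit the calls at single CpGs. At a median of 16 reads per listed CpG, 5.5% of simulated changes of 30 points were recovered in the WT doxorubicin comparison, with 200 changed per size. In the untreated genotype comparison, with 60000 changed per size, 13.05% were recovered.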

Other observations

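The comparison of strands was planned; the other values here were looked up after the main results were seen.

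Besides the chromosomes named in the report, chromosomes 2, 10 and 17 had a relative depth of 1.15, 1.17 and 1.20 in Pml KO untreated, and 1.15, 1.16 and 1.20 in Pml KO doxorubicin. In the WT libraries these chromosomes lay between 0.975 and 1.04. Y-chromosome CpGs were listed in every library, from 7637 in Pml KO doxorubicin to 7865 in Pml KO untreated. Mitochondrial CpGs had 197.5, 209.3, 151.8 and 194.8 times the reads of the median autosome in WT untreated, WT doxorubicin, Pml KO untreated and Pml KO doxorubicin.

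CpG-dense windows at 40 to 60% in all 4 libraries, a level that imprinted regions hold when only one parental copy is methylated, numbered 155. Their genes were not analysed here.

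Some CpGs read as unmethylated between highly methylated neighbours. Of 1266395 CpGs with neighbours at 70% or more on both sides in all 4 libraries, 12239 were at 5% or less in all 4, but 23 were so in both Pml KO libraries alone and 57 in both WT libraries alone. On the X chromosome 9 of 22244 were low in all 4, and over 488 autosomal windows of 5 Mb the share ran from 0.00% to 7.03%, with a median of 0.668%. Of the 23 CpGs, 14 lay on chromosome 1. No explanation for these was tested.

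Neighbours of called CpGs differed less between the treatments than between the genotypes. Beside CpGs called lower in WT doxorubicin against WT untreated, the nearest CpG within 200 bp differed by -4.40 points on average, and 51.0% of these neighbours were lower. Beside CpGs called lower in Pml KO untreated against WT untreated, 70.7% were lower. Within single libraries, the strands of a CpG differed by the same thresholds at 1.01% of CpGs in WT untreated and at 1.32% in Pml KO doxorubicin, over 1451924 and 1198281 CpGs compared.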
